A study of Rattus norvegicus with 4 samples.

How the data were processed

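RNA of rat brain fractions was measured on dual-colour Agilent cDNA arrays. Each array set a fraction described by the labels as rich in dendritic mRNA against its reference fraction: the heavy portion of polysomes (HP) against the light portion (LP), or synaptosomes (D4) against extrasynaptosomal material (C2). Both preparations came from rats with and without MECS, a maximum electroconvulsive seizure. Per the labels, the RNA was amplified once before labelling, from 1000 ng of 3 rats per fraction for HP and LP and from 330 ng of 1 rat per fraction for D4 and C2. The 4 groups held 2 replicates each, and each replicate was hybridised in 2 dye orientations, which gave 16 arrays. A replicate here is a slide with its dye swap, and n counts these. The labels do not state whether the 2 replicates of a group came from separate rats.

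Each deposited array file holds spot intensity values in both channels from Agilent Feature Extraction, with local background values and with processed signals that the software had corrected for background and dye. Per the file headers, version 6.1.1 read 14 arrays and version 5.1.1 read 2 arrays. The deposited ratio column of each array is log10 of the red over the green processed signal. The authors also deposited 1 log10 value per probe and group, which was checked against the mean ratio over the group's 4 arrays, with the swapped arrays turned. In 3 groups it equals that mean but for its sign, and in the HP/LP group without MECS it correlates with it at r = -0.979 (slope -1.01). That table holds a value for 11664 and 8530 of 12276 probes in the HP/LP groups without and with MECS, and for 5366 and 4362 in the D4/C2 groups. The rule behind the blank values is not stated.

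The direction of every ratio between fractions rests on the label protocols alone. They put HP and D4 in Cy3 on the first orientation and in Cy5 on the swapped one. The sentence on swapping in the D4/C2 labels names HP and LP. Under these dyes the authors' table runs from the reference to the dendritic fraction, since its sign is opposite to that of the turned ratios in all 4 groups. The labels do not give the table's direction. If the dyes were the other way round, every sign of an HP/LP or D4/C2 ratio, and of a MECS effect on such a ratio, would turn and the counts of higher and lower features would trade places, while sizes, p-values and the mean signals would stay. The analysis of the genes most abundant in HP or D4 would then pick the genes at the opposite end, which the report gives as well.

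The spot means were corrected with the normexp method of limma 3.58.1 (R 4.3.3; offset 50) against the local background medians and normalised by loess within each array, with control spots at weight 0 and spots that Feature Extraction marked as non-uniform or as population outliers left out. Probes well above background in at least 1 channel on at least 4 of the 16 arrays were kept, 14790 of 14794. The probe with the highest mean signal stood for a gene, which gave 13184 features. Ratios were turned to HP over LP or D4 over C2, and the 2 dye orientations of a replicate were averaged; a feature missing in either orientation was missing in that replicate. The 8 replicate ratios were fitted together with limma (lmFit and eBayes, 1 mean per group, 4 residual degrees of freedom), and p-values were adjusted by Benjamini and Hochberg within each result with a threshold of 0.05. A dye swap repeats the same extracts and was not counted as a replicate. Standard errors (SE) are those of the fit. Contrasts were each group's ratio, the difference of ratios with and without MECS in each preparation, and the difference in the mean signal of both channels (after quantile normalisation between arrays), since no array set MECS against non-MECS RNA. Replicate numbers were tried as a block only as an alternative.

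The files give GenBank keys and descriptions but no gene symbols. Symbols for the lists were matched by hand from the descriptions before any value was read and cover 431 probes with 335 symbols, and none of the keys matched the reference table. The 20 gene lists cover dendritically localized mRNAs, excitatory postsynaptic components, presynaptic and vesicle components, inhibitory neuron markers, neuropeptide and dense-core vesicle genes, immediate early genes, heat shock and chaperones, ribosomal proteins, translation factors, RNA transport and granule proteins, nuclear-encoded oxidative phosphorylation, glycolysis, proteasome, cytoskeleton, voltage-gated channels, and markers of oligodendrocytes and myelin, astrocytes, microglia, endothelial, mural and blood cells, and choroid plexus and ependyma. They were tested with limma's camera (preset correlation 0.01, two-sided, at least 5 members with a value in all 8 replicates), with Benjamini-Hochberg adjustment over 160 tests, 20 lists in 8 results. Of these tests 49 passed, and 0 of the 49 held with an estimated correlation, for which the smallest adjusted p was 0.3532. Only members with a value in all 8 replicates entered the set test, while the counts and medians given for a list cover all its measured genes. The set test used 12 of 17 microglia markers, 15 of 21 immediate early genes and 47 of 54 ribosomal protein genes. Overlaps of calls were tested with Fisher's exact test, two-sided. Of the microglia markers, 1 counts in its list and is not reported here by name.

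Tests, lists, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, among features with a descriptive gene name that passed with the same sign in both replicates, the 10 with the largest log2 value in each direction; where none passed, the 3 with the smallest p in each direction, as values only. It also takes up to 4 members per list with the smallest adjusted p, and 14 fixed genes. It was written for gene symbols and applied to descriptive names, of which 5707 features carry one. Clone names from a gene prediction program were excluded only after the named genes had been seen. Array quality weights, leaving out replicate 1 of both HP/LP groups, a crossed pairing for the HP/LP mean signals, and the genes at the opposite end were chosen after seeing the data.

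Alternatives covered the software's processed values, background subtraction, the normalisation within and between arrays, the filter, the treatment of dye swaps, separate fits, the variance model, a replicate block, the mean over a gene's probes, and leaving out each replicate. The same steps were tested on simulated arrays. These gave every probe of a preparation the same spread between replicates, taken from the real arrays as 1 value. Real spreads differ between features, so the rates below need not carry over to the real calls. Of 100 features changed by a log2 of 0.8, 96 were found in the D4/C2 comparison and 93 in the HP/LP comparison without MECS. In the MECS effect on HP/LP, 61 of 100 were found at 0.8 and 100 of 100 at 1.6, and in the MECS effect on D4/C2, 0 of 54 were found at 0.4. Unchanged features made up 33 of 226 calls in HP/LP without MECS (14.6%) and 19 of 180 in the MECS effect on HP/LP (10.6%), above the threshold of 5%, and 8 of 203 and 10 of 205 in D4/C2 without and with MECS. The number of arrays limits the precision.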

Results

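The series compared RNA between brain fractions of rats on 16 arrays. In the polysome preparation, HP, the heavy portion of polysomes that the labels describe as rich in RNA granules, was set against LP, the light portion. In the synaptosome preparation, D4, a purified synaptosome fraction, was set against C2, the extrasynaptosomal reference. Each preparation was made without and with a maximum electroconvulsive seizure (MECS), with 2 replicates per group and 2 dye orientations per replicate. Median spot signals were 546 to 1262 in Cy3 and 128 to 1184 in Cy5 on the HP/LP arrays, and 272 to 593 in Cy3 and 51.1 to 149 in Cy5 on the D4/C2 arrays. Between 68.4% and 98.5% of probes were well above background in Cy5 on the HP/LP arrays, and between 34.7% and 93.4% on the D4/C2 arrays.

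All directions between fractions rest on the dyes named in the label protocols. The authors' table of values has the opposite sign under those dyes, and its direction is not stated, so an exchange of the dyes would turn every sign of the HP/LP and D4/C2 ratios given here. Across genes, the 2 D4/C2 replicates correlated with r = 0.87 without MECS and 0.75 with MECS, and the 2 HP/LP replicates with r = 0.23 and 0.11. The dye orientations of a replicate, turned to the same direction, correlated with r = 0.71 and 0.81 (D4/C2 without MECS) and 0.57 and 0.64 (with MECS). For HP/LP they correlated with r = -0.13 and 0.80 without MECS and with r = -0.19 and -0.02 with MECS. In 3 of the 4 HP/LP replicates the part of the ratio that stayed with the dye had a larger spread (SD) than the part that stayed with the fraction: 0.323 against 0.285 in replicate 1 without MECS, and 0.263 against 0.220 and 0.161 against 0.159 with MECS. Genes are not independent replicates.

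The HP/LP comparison without MECS asks which mRNAs the granule-rich polysome portion holds more or less of. The named genes lower in HP than in LP include some for protein folding, RNA handling and cell structure. Hspa8, the constitutive cytosolic Hsp70 chaperone, was 2.40-fold lower (log2 -1.26 ± 0.16, SE, n = 2, adjusted p = 0.0237), and BiP, the Hsp70 chaperone of the endoplasmic reticulum, was 2.38-fold lower (log2 -1.25 ± 0.11, n = 2, adjusted p = 0.0162). The NonO/p54nrb homolog, a nuclear RNA-binding protein, was 3.35-fold lower (log2 -1.75 ± 0.18, n = 2) and Ddx5, the p68 RNA helicase, 2.69-fold lower (log2 -1.43 ± 0.17, n = 2). Alpha catenin, which links cadherins to actin, had the largest fall among genes with a descriptive name, 3.50-fold (log2 -1.81 ± 0.21, n = 2). Polyubiquitin C (log2 -1.35), the M4 protein homolog (-1.36), maf10 (-1.34), the neuropeptide gene Adcyap1 (-1.29) and the elongation factor gene Eef1a1 (-1.28) were also lower. In all, 86 of 13141 features were lower in HP and 2 were higher by limma, and all 88 went the same way in both replicates, from which they were picked. On simulated arrays, which gave every probe the same spread between replicates, 14.6% of the calls in this comparison were unchanged features. That share need not hold for the real calls. The calls also rest on 1 estimate of the spread shared by the 4 groups. Among features tested in both preparations, they did not hold without either D4/C2 replicate of the group without MECS. The 2 higher ones were Atp5pd, a subunit of ATP synthase (1.46-fold, log2 0.54 ± 0.077, n = 2), and an unannotated Incyte clone (log2 0.58), singled out after its value was seen. The count was 325 without replicate 1, 2 without replicate 2, and 0 with the software's processed values, with the spread of ratios scaled between arrays, or with HP/LP fitted alone.

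Several gene lists leaned one way in HP without MECS, none of them passing with an estimated correlation. Of 17 RNA transport and granule protein genes, 3 fell and 14 did not pass (9 fell adjusted over the list alone; median log2 -0.32, adjusted p = 1.52e-05 and adjusted p = 0.353 with an estimated correlation). The 3 were Ddx5, the dynein intermediate chain gene Dync1i1 (-1.21) and the dynactin gene Dctn1 (-0.84). Of 20 cytoskeleton genes, 5 fell and 15 did not pass (8 fell adjusted over the list alone; median -0.36, adjusted p = 6.70e-05 and adjusted p = 0.353 with an estimated correlation), among them Tuba1a (-0.84), Tubb2 (-0.83), Map4 (-0.96) and Nefl (-0.62). Of 13 glycolysis genes, all had a negative ratio and 1 fell, Pfkp (-1.12), with 6 adjusted over the list alone (median -0.28, adjusted p = 1.52e-05 and adjusted p = 0.419 with an estimated correlation). Of 20 heat shock and chaperone genes, 2 fell, Hspa8 and Cct2 (-0.72), and 18 did not pass, with 11 lower adjusted over the list alone (median -0.57, adjusted p = 1.20e-04, adjusted p = 0.528 with an estimated correlation, and adjusted p = 0.0955 with a median of -0.27 without replicate 2). The BiP feature, a chaperone named above as lower, carried a GenBank key without a list symbol and is not counted among these heat shock members. On the arrays with HP in Cy3 the RNA transport, cytoskeleton and glycolysis lists lost their calls (adjusted p = 0.0760, 0.254 and 0.275, medians -0.12, -0.18 and -0.16). Without replicate 1 the glycolysis median was -0.75 and that of the cytoskeleton -0.62, and without replicate 2 the RNA transport median was -0.20. Each of these 4 lists kept its call in 16 of 17 alternatives besides the estimated correlation.

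Ribosomal protein mRNAs had the opposite lean: 48 of 54 had a positive ratio, 0 passed in limma over all features or adjusted over the list alone, and the median was 0.21 (adjusted p = 6.74e-08 and adjusted p = 0.632 with an estimated correlation). That median was 0.03 without replicate 1 (adjusted p = 0.354). The proteasome list (18 genes, 0 passed; median 0.14, adjusted p = 0.0387 and adjusted p = 0.731 with an estimated correlation) turned to a median of -0.09 without replicate 1. Oxidative phosphorylation (28 genes; 1 rose, Atp5pd, and 1 fell, Ndufs1 at -0.95; 3 and 2 adjusted over the list alone) had a median of 0.04 (adjusted p = 0.0398, adjusted p = 0.731 with an estimated correlation; adjusted p = 0.388 without replicate 1) that turned to -0.01 under the strict filter and -0.14 on the arrays with HP in Cy5. Translation factors (20 genes; 1 fell, Eef1a1; 2 adjusted over the list alone) had a median of -0.09 (adjusted p = 0.0487 and adjusted p = 0.632 with an estimated correlation) and of 0.03 without replicate 2 (adjusted p = 0.747). Oligodendrocyte and myelin markers (13 genes; 0 passed, 4 fell adjusted over the list alone; median -0.23, adjusted p = 0.0135) and astrocyte markers (11 genes; 0 passed, 4 fell adjusted over the list alone; median -0.17, adjusted p = 0.0218) each had an adjusted p of 0.632 with an estimated correlation. Without replicate 2 their adjusted p were 0.191 and 0.177, and without replicate 1 that of the astrocyte list was 0.0527. On the arrays with HP in Cy3 the astrocyte median was 0.06 and the oligodendrocyte list lost its call (median -0.13, adjusted p = 0.261). Of the 17 alternatives, ribosomal proteins kept their call in 15, oligodendrocyte markers in 14, astrocyte markers in 11, the proteasome in 9 and oxidative phosphorylation and translation factors in 6 each. Without replicate 1 the medians of translation factors, oxidative phosphorylation and astrocyte markers were -0.18, 0.07 and -0.30, and without replicate 2 those of ribosomal proteins, the proteasome and oxidative phosphorylation were 0.40, 0.33 and 0.11.

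The lists for synapses and dendrites did not pass in HP. The 18 dendritically localized mRNAs had a median log2 HP/LP of -0.03 (adjusted p = 0.789), with 1 of them lower, Eef1a1, and the 17 excitatory postsynaptic genes had an adjusted p of 0.601 with 0 called. Adjusted p was 0.511 for 15 presynaptic genes, 0.705 for 7 inhibitory neuron markers, of which Gad, the GABA-synthesising enzyme, fell (-1.06), and 0.625 for 8 neuropeptide genes, of which Adcyap1 fell. It was 0.935 for 21 immediate early genes, 0.555 for 14 voltage-gated channels, 0.424 for 17 microglia markers, 0.556 for 15 endothelial, mural and blood markers and 0.705 for 6 choroid plexus markers.

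**Figure D1:**
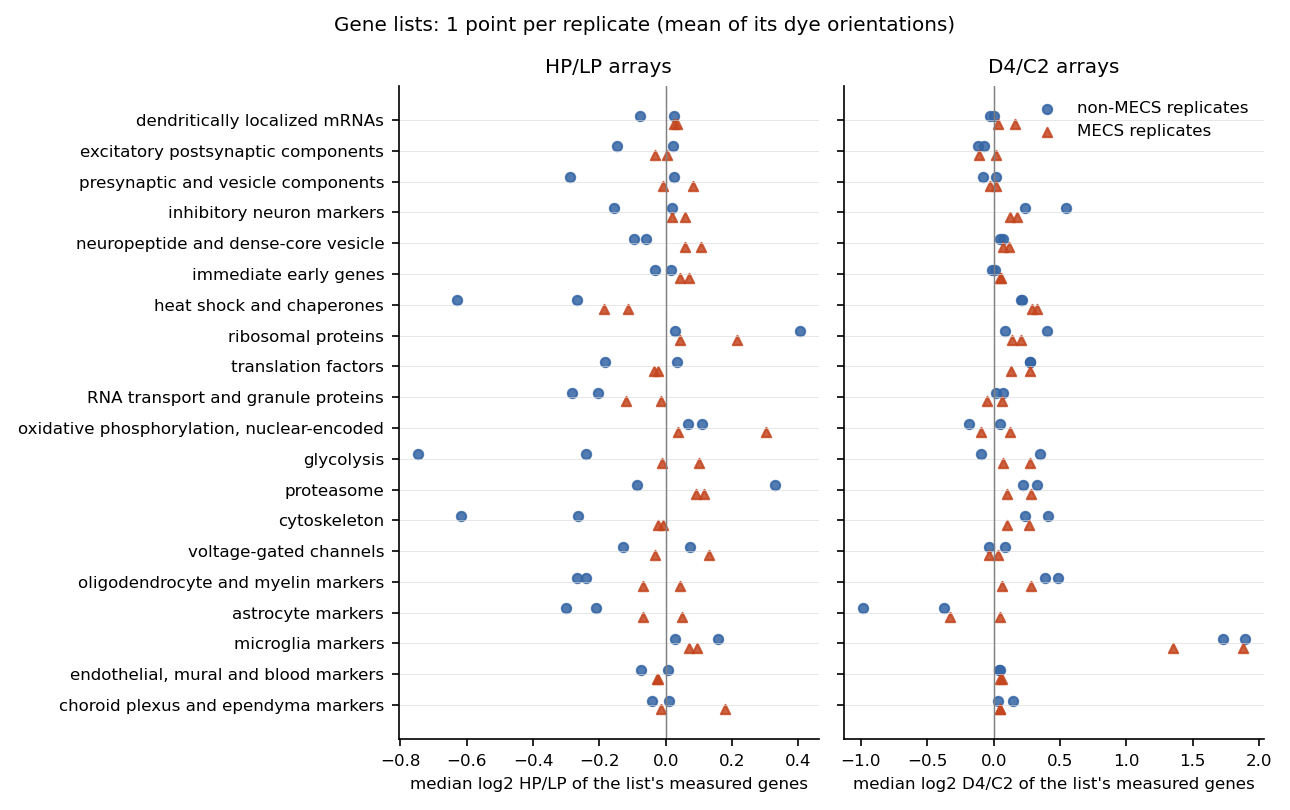
Median log2 ratio of each gene list (1 line of points each) per replicate on the HP/LP arrays (left) and the D4/C2 arrays (right), with circles for replicates without MECS and triangles for replicates with MECS. The microglia list stands apart on the D4/C2 arrays, with a median of 1.81 over the group without MECS and 1.67 with MECS.

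After MECS, no single gene passed in HP against LP: limma called 0 of 13138 features, with 575 at an unadjusted p below 0.05 and a smallest adjusted p of 0.123. The smallest p belonged to Adcyap1 (log2 -0.76 ± 0.081, n = 2, adjusted p = 0.123), the transitional endoplasmic reticulum ATPase (-1.07) and a lipoprotein-binding protein (-0.86) on the low side. On the high side they belonged to a scg10-like protein (0.57, adjusted p = 0.247), cathepsin B (0.39) and Atp5pd (0.34). Of the 86 features lower in HP without MECS, 78 of the 81 measured in both MECS replicates were below 0 in both (96.3%), against 22.7% of all features. Of 28 oxidative phosphorylation genes 23 had a positive ratio, with a list median of 0.16 that turned to -0.06 with median centring. Its adjusted p was 1.95e-04, and adjusted p = 0.632 with an estimated correlation. Of 18 proteasome genes 16 were positive, with a median of 0.16 that turned to -0.03 with median centring (adjusted p = 4.44e-04, and adjusted p = 0.632 with an estimated correlation). Of 54 ribosomal protein genes 46 were positive, with a median of 0.13 that turned to -0.13 with median centring (adjusted p = 1.33e-05, and adjusted p = 0.707 with an estimated correlation). Heat shock genes leaned to LP, with 13 of 20 negative and a median of -0.16 (adjusted p = 0.00409, and adjusted p = 0.632 with an estimated correlation). So did RNA transport genes, with 13 of 17 negative and a median of -0.07 that was 0.09 on the arrays with HP in Cy3 (adjusted p = 0.00784, and adjusted p = 0.419 with an estimated correlation). In these 5 lists 0 members passed, and adjusted over the list alone 2 RNA transport genes were lower and 0 in the other 4. Without replicate 2 all 5 lost their call, with adjusted p of 0.718, 0.0792, 0.638, 0.0533 and 0.419 in the order given. The medians were then 0.04, 0.09 and 0.04 for oxidative phosphorylation, the proteasome and ribosomal proteins and -0.01 for RNA transport, and without replicate 1 those of oxidative phosphorylation, ribosomal proteins and RNA transport were 0.30, 0.22 and -0.12. Of 17 alternatives the heat shock list kept its call in 16, RNA transport and ribosomal proteins in 15, oxidative phosphorylation in 14 and the proteasome in 13. The strict filter, which tests fewer features, called 11 features lower in HP.

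The MECS effect on HP/LP, the ratio with MECS minus the ratio without, asks which mRNAs move between the polysome portions after the seizure. All 13 glycolysis genes had a higher HP/LP ratio after MECS, with Aldoc at 0.82 and Eno2 at 0.69. The list's median difference was 0.51 (adjusted p = 6.74e-08, and adjusted p = 0.353 with an estimated correlation), and 0.07 with median centring (adjusted p = 0.927). Without replicate 2 of the group without MECS it was 0.21 (adjusted p = 0.0126). Of 19 cytoskeleton genes, 17 had a higher ratio, with the tubulin genes Tubb2 at 0.97 ± 0.12 (SE, n = 2 against 2, adjusted p = 0.548) and Tuba1a at 0.75. The list's median was 0.35 (adjusted p = 6.74e-08, and adjusted p = 0.353 with an estimated correlation), and 0.18 with median centring (adjusted p = 0.0459). Apart from the estimated correlation, it kept its call in the 19 alternatives run for it. In either list 0 members passed over all features and 3 rose adjusted over the list alone. Limma called 0 of 13134 features, with 367 at an unadjusted p below 0.05 and a smallest adjusted p of 0.548. The other values with the smallest p were KAP3B at 0.85, LOMP at -0.55, the receptor kinase GRK4 at -0.64 (1 MECS replicate) and CGI-83 at -0.34.

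Other lists also differed between HP/LP with and without MECS. Of 17 RNA transport genes 12 had a higher ratio after MECS (median 0.29, adjusted p = 2.60e-04, and adjusted p = 0.353 with an estimated correlation), and adjusted over the list alone 1 rose. The list's adjusted p was 0.0623 without MECS replicate 1 and 0.0726 with median centring (median 0.12), and its median was 0.07 and 0.16 without replicates 2 and 1 of the group without MECS. Of 11 astrocyte markers 9 had a higher ratio and 2 rose adjusted over the list alone (median 0.37, adjusted p = 0.00435, and adjusted p = 0.632 with an estimated correlation), and with median centring the median was 0.06 and the camera direction turned. The list's adjusted p was 0.163 without replicate 2 of the group without MECS and 0.0819 without MECS replicate 2. Of 13 oligodendrocyte markers 11 had a higher ratio (median 0.29, adjusted p = 0.00329, and adjusted p = 0.528 with an estimated correlation), and with median centring the median was 0.0088 (adjusted p = 0.670). Of 20 heat shock genes 14 did (median 0.26, adjusted p = 0.00329, and adjusted p = 0.632 with an estimated correlation), and with median centring the median was 0.0054 and the camera direction turned. Without replicate 2 of the group without MECS, the oligodendrocyte list had a median of 0.13 and an adjusted p of 0.233, and the heat shock list a median of -0.07 and an adjusted p of 0.988. Of 54 ribosomal protein genes 38 had a lower ratio, with a median of -0.09 that turned to 0.02 when the spread of ratios was scaled (adjusted p = 0.00815, and adjusted p = 0.783 with an estimated correlation). The ribosomal median was 0.12 without replicate 1 of the group without MECS (adjusted p = 0.304) and 0.0023 without MECS replicate 1 (adjusted p = 0.894). Of 8 neuropeptide genes 5 had a higher ratio and 1 rose adjusted over the list alone (median 0.16, adjusted p = 0.0309, and adjusted p = 0.528 with an estimated correlation). That list lost its call without each of the 4 replicates in turn, with adjusted p between 0.0856 and 0.199, and with median centring (median 0.01, adjusted p = 0.952). Without replicate 1 of the group without MECS the oligodendrocyte and heat shock medians were 0.17 and 0.39, and without replicate 2 of that group the ribosomal and neuropeptide medians were -0.28 and 0.35. Without MECS replicate 1 the neuropeptide median was 0.24, and without MECS replicate 2 the astrocyte, oligodendrocyte, heat shock and ribosomal medians were 0.23, 0.18, 0.14 and -0.20. With replicate 2 alone in both groups the ribosomal list passed in the opposite direction (median 0.19, adjusted p = 0.00532). Of 19 alternatives the heat shock and oligodendrocyte lists kept their call in 17, RNA transport in 16, astrocyte markers and ribosomal proteins in 14, and neuropeptide genes in 6 of 18.

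**Figure D2:**
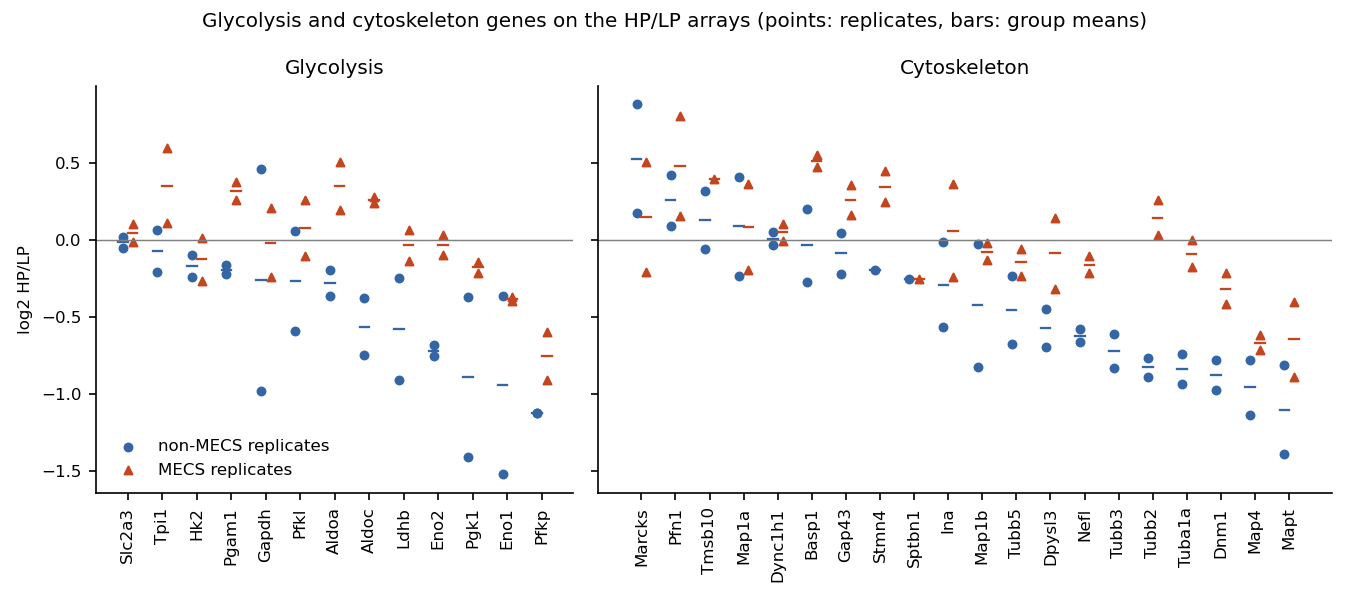
Log2 HP/LP of each measured glycolysis gene (left) and cytoskeleton gene (right), with circles for replicates without MECS, triangles for replicates with MECS and bars for group means; a group with 1 point had the other replicate missing in a dye orientation. All 13 glycolysis genes and 17 of 19 cytoskeleton genes had a higher mean with MECS, and the median differences shrank to 0.07 and 0.18 with median centring.

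The D4/C2 comparison without MECS asks which mRNAs the synaptosome fraction holds more or less of than its reference. Microglia markers were higher in D4: Aif1, a calcium-binding protein of microglia, was 11.7-fold higher (log2 3.54 ± 0.27, SE, n = 2, adjusted p = 1.11e-04), Ctss, the lysosomal protease cathepsin S, 7.61-fold (2.93 ± 0.15, n = 2, adjusted p = 1.79e-05) and Tyrobp, an immune signalling adaptor, 6.01-fold (2.59 ± 0.16, n = 2, adjusted p = 4.38e-05). Ttr, the thyroid hormone carrier made by the choroid plexus, had the largest rise, 29.3-fold (4.87 ± 0.23, n = 2, adjusted p = 1.49e-05). Prostaglandin-H2 D-isomerase was 13.1-fold higher (3.71 ± 0.33, n = 2), the tetraspanin Tspan5 13.8-fold (3.78 ± 0.23, n = 2) and Vim, the intermediate filament vimentin, 6.96-fold (2.80 ± 0.20, n = 2). PP2A subunit B'-beta (2.71), p41-Arc, a subunit of the actin-nucleating Arp2/3 complex (2.49), and EN-7 (2.47) completed the 10 largest rises among genes with a descriptive name that were measured in both replicates. Under the same limits the largest falls, after a lowest value of -3.93 among all called features, were RoBo-1 (-3.24 ± 0.30, n = 2), carnitine palmitoyltransferase I, which carries fatty acids into mitochondria (-2.97), the transporter mtp2 (-2.83), F alloantigen (-2.81), smooth muscle gamma-actin (-2.79), Impact (-2.79), leukotriene A4 hydrolase (-2.78), Ese2L (-2.75), cca2 (-2.73) and phosphatidylinositol transfer protein beta (-2.69). Limma called 805 features higher and 787 lower of 13110, and 694 in all without replicate 1. For 111 genes called lower that have other array elements, those elements had a median log2 D4/C2 of -0.04, against -1.21 for the tested elements. For 115 genes called higher the medians were 0.20 and 0.68. The tested elements had the highest mean signal of their gene and were picked because they were called, which can by itself leave the others nearer 0.

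Of 17 microglia markers, 11 rose in D4, 2 fell and 4 did not pass (12 and 2 adjusted over the list alone; median 1.81, adjusted p = 2.70e-05 and adjusted p = 0.528 with an estimated correlation). Under the strict filter the median was 1.05 and the list lost its call (adjusted p = 0.0686), while with processed values the median was 2.73. Among the others that rose were the complement genes C1qa (3.15, 1 replicate), C1qb (1.84) and C1qc (1.40), the receptor genes Csf1r (2.30) and Cx3cr1 (1.52), and Fcer1g (2.43), while Ptprc (-1.65) was among those that fell. The C1q genes, Cx3cr1 and Ptprc were singled out after their values were seen. Of 13 oligodendrocyte and myelin markers, 5 rose and 8 did not pass (7 rose adjusted over the list alone; median 0.49, adjusted p = 0.00323 and adjusted p = 0.528 with an estimated correlation), with Aspa at 1.56, Tf at 1.06 and Mal at 0.84. Of 11 astrocyte markers, 3 fell, 1 rose and 7 did not pass (7 and 1 adjusted over the list alone; median -0.52, adjusted p = 0.0188, adjusted p = 0.632 with an estimated correlation, and adjusted p = 0.190 without replicate 1). The astrocyte median was -0.37 without replicate 1 and -0.98 without replicate 2. Aldoc (-0.86), Dio2 (-0.83) and Gfap (-0.52) fell, and Vim, which other cell types also express, rose. Of 15 endothelial, mural and blood markers 3 rose, Tagln (1.20), Col3a1 (1.11) and Hba1 (0.73), without a list call (adjusted p = 0.241). Of 6 choroid plexus markers 2 rose, Ttr and Folr1 (0.40; list adjusted p = 0.0577). Of 16 alternatives the oligodendrocyte list kept its call in all 16, microglia in 15 and astrocyte markers in 10.

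**Figure D3:**
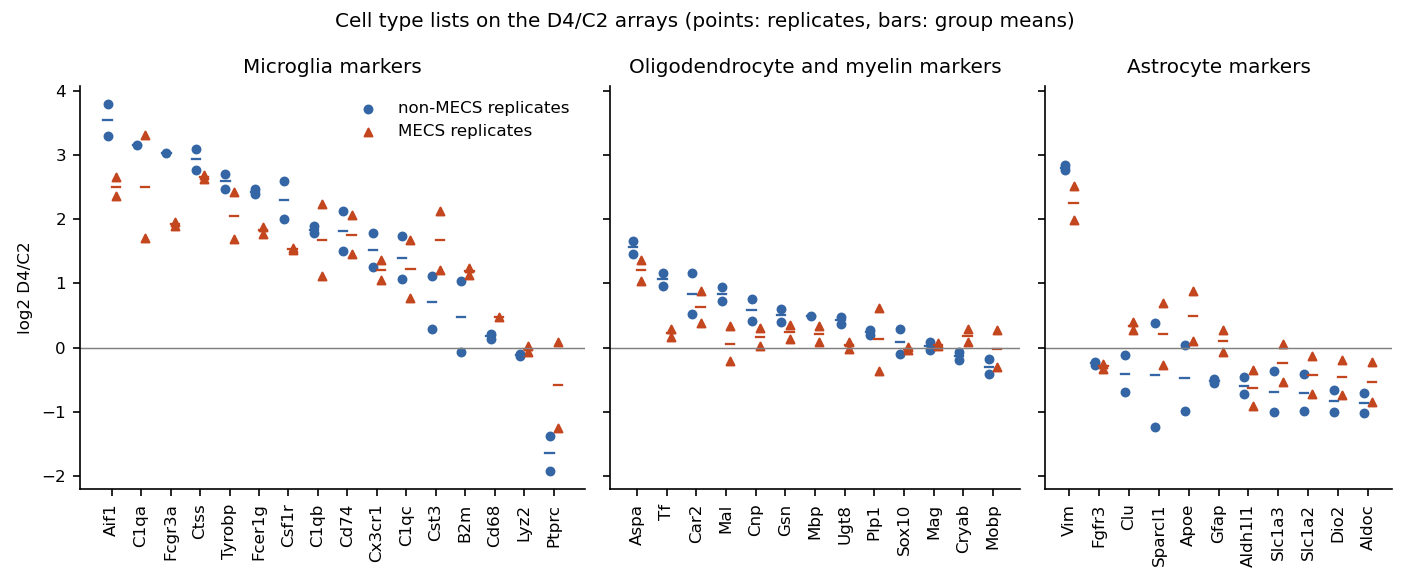
Log2 D4/C2 of 16 of the 17 measured microglia markers and of each measured oligodendrocyte and astrocyte marker, with circles for replicates without MECS, triangles for replicates with MECS and bars for group means; a group with 1 point had the other replicate missing in a dye orientation. The medians of the full lists without MECS were 1.81, 0.49 and -0.52.

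Genes of protein synthesis and turnover and of the cytoskeleton leaned to D4. Of 21 cytoskeleton genes, 9 rose and 12 did not pass (9 rose and 1 fell adjusted over the list alone; median 0.30, adjusted p = 0.0156 and adjusted p = 0.473 with an estimated correlation), among them Actb, beta-actin (1.80 ± 0.11, n = 2), Tmsb10 (1.76), Tubb5 (1.34) and Basp1 (1.22). Of 20 translation factors, 6 rose and 14 did not pass (7 rose adjusted over the list alone; median 0.32, adjusted p = 0.00429, adjusted p = 0.528 with an estimated correlation, and adjusted p = 0.0641 without replicate 2), with Eef1a1 at 1.42 and Eef1g at 0.99. Of 18 proteasome genes, 8 rose, 1 fell and 9 did not pass (8 and 1 adjusted over the list alone; median 0.31, adjusted p = 0.00169 and adjusted p = 0.667 with an estimated correlation). Psme1 (1.45) and Psmb9 (1.14), parts of the interferon-induced proteasome of antigen processing, rose and Psma3 (-1.98) fell. Of 54 ribosomal protein genes, 15 rose, 4 fell and 35 did not pass (21 and 6 adjusted over the list alone; median 0.25, adjusted p = 0.00497, adjusted p = 0.780 with an estimated correlation, and adjusted p = 0.253 with a median of 0.08 without replicate 2), with Rpl14 at 1.18 and Rps15a at -1.26. Without replicate 1 the ribosomal median was 0.40. The ribosomal list lost its call with processed values, with median centring and with D4 in Cy3 (adjusted p = 0.198, 0.480 and 0.493, medians 0.16, 0.17 and 0.14). The cytoskeleton list lost its call with median centring and with D4 in Cy5 (adjusted p = 0.0708 and 0.177), and the proteasome list with median centring and under the strict filter (adjusted p = 0.0597 and 0.0686).

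Synaptic and dendritic gene lists did not pass in D4. Of 19 dendritically localized mRNAs, 4 rose, 2 fell and 13 did not pass (median 0.01, adjusted p = 0.686). Actb, Eef1a1, the scaffold gene Shank1 (0.60 ± 0.13, n = 2) and Rgs4 (0.54) rose, and Ntrk2, the BDNF receptor (-0.62), and Dlg4, the postsynaptic scaffold PSD-95 (-0.48 ± 0.11, n = 2), fell. Camk2a (-0.04), Nrgn (0.23), Arc (0.21), Homer1 (0.11), Fos (-0.30), Egr1 (0.63) and Mbp (0.49, 1 replicate) did not pass. Of 17 excitatory postsynaptic genes 1 rose and 2 fell, among them Grin2c (-0.62; list adjusted p = 0.625). Of 15 presynaptic genes Dnm1, the vesicle-fission GTPase dynamin 1, rose (0.94) and Sv2a, a synaptic vesicle protein, fell (-1.50; list adjusted p = 0.927). Single members rose in the inhibitory neuron list (Gad 0.61; list adjusted p = 0.403), the neuropeptide list (Adcyap1 0.91; 0.287) and the immediate early gene list (Rgs2 1.26; 0.714). Heat shock genes (4 of 20 rose, with Cct2 at 1.16 and adjusted p = 0.109), RNA transport genes (Ddx5 at 1.23 rose, Syncrip at -2.30 and Kif3a at -1.89 fell; 0.913), glycolysis (4 rose, with Eno2 at 1.15, and Aldoc fell; 0.273), oxidative phosphorylation (3 of 28 fell, with Cox4i1 at -0.90; 0.550) and 14 voltage-gated channels (0 called; 0.714) did not pass as lists.

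With MECS, microglia markers and Ttr were again higher in D4 than in C2. Ttr was 17.7-fold higher (log2 4.15 ± 0.23, SE, n = 2, adjusted p = 8.73e-05), Ctss 6.28-fold (2.65 ± 0.15, n = 2, adjusted p = 8.73e-05) and Aif1 5.66-fold (2.50 ± 0.27, n = 2, adjusted p = 0.00132). Tspan5 (3.76), an epidermal keratin (2.90), C1qa (2.51), PP2A subunit B'-beta (2.47), N-acetylneuraminic acid 9-phosphate synthetase (2.40), HBRM (2.35) and an epididymal secretory protein (2.28) made up the other large rises among genes with a descriptive name. Among such genes the largest falls, after a lowest value of -2.26 among all called features, were mtp2 (-2.22 ± 0.11, n = 2), the nicotinic receptor delta subunit (-2.06), a 54 kDa oligoadenylate synthetase-like protein (-2.05), Impact (-1.94), the cholesterol transporter Abca1 (-1.93), intestinal trefoil factor (-1.93), a Pol polymerase (-1.88), integrin alpha-4 (-1.86), ABH (-1.85) and leukotriene A4 hydrolase (-1.85). Limma called 264 features higher and 427 lower of 13109, and 448 in all without replicate 2. Of these, 248 of the higher and 423 of the lower features were also called without MECS, against 16.2 and 25.6 for independent lists. Both sets of calls use the same estimate of the spread per feature, so they are not independent. The ratios with and without MECS correlated across genes with r = 0.90 (Spearman's rho 0.62).

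Of 17 microglia markers, 12 rose, 1 fell and 4 did not pass (14 and 1 adjusted over the list alone; median 1.67, adjusted p = 2.19e-10 and adjusted p = 0.383 with an estimated correlation). Of 20 heat shock genes, Hspa8 (0.98), Cct2 (0.81) and Tcp1 (0.62) rose and 17 did not pass (7 rose adjusted over the list alone; median 0.29, adjusted p = 6.70e-05 and adjusted p = 0.528 with an estimated correlation). With median centring the heat shock median was 0.09 (adjusted p = 0.801) and Hspa8 turned to -0.0032. Of 20 translation factors 3 rose, 4 adjusted over the list alone (median 0.15, adjusted p = 0.00171, and adjusted p = 0.528 with an estimated correlation), and with median centring the median was 0.05 (adjusted p = 0.936). Of 21 cytoskeleton genes 5 rose, 6 adjusted over the list alone, with a median of 0.15 that turned to -0.03 with median centring (adjusted p = 0.00145, and adjusted p = 0.353 with an estimated correlation). Of 54 ribosomal protein genes 6 rose, with a median of 0.19 that turned to -0.59 with median centring, where the list passed in the opposite direction (adjusted p = 4.12e-09), and to -0.03 with the software's processed values. Adjusted over the list alone 12 rose and 3 fell (list adjusted p = 2.86e-04, and adjusted p = 0.731 with an estimated correlation). Of 18 proteasome genes 2 rose and 1 fell, 5 and 1 adjusted over the list alone, with a median of 0.19 that turned to -0.13 with median centring (adjusted p = 0.00354, and adjusted p = 0.707 with an estimated correlation). Of 13 glycolysis genes 3 rose, with a median of 0.18 that turned to -0.21 with median centring (adjusted p = 0.0203, and adjusted p = 0.632 with an estimated correlation). Adjusted over the list alone 4 rose and 1 fell. Of 13 oligodendrocyte markers 1 rose, Aspa at 1.20, also adjusted over the list alone, with a median of 0.16 that turned to -0.22 with median centring (adjusted p = 0.0132, and adjusted p = 0.632 with an estimated correlation). Neuropeptide genes (1 of 8 rose, Adcyap1 at 0.85, median 0.06, adjusted p = 0.0397) and choroid plexus markers (1 of 6 rose, Ttr, median 0.04, adjusted p = 0.0398) each had an adjusted p of 0.528 with an estimated correlation. Without replicate 2, adjusted p was 0.0537 for translation factors, 0.0690 for the cytoskeleton, 0.244 for glycolysis and for the proteasome, 0.489 for oligodendrocyte markers, 0.187 for neuropeptide genes and 0.0959 for choroid plexus markers. The medians were then 0.10 for the cytoskeleton and for the proteasome, 0.07 for glycolysis, 0.06 for oligodendrocyte markers and 0.12 for neuropeptide genes. Without replicate 1 the adjusted p was 0.0661 for choroid plexus markers, and the medians of translation factors, the cytoskeleton, the proteasome and oligodendrocyte markers were 0.27, 0.26, 0.28 and 0.28. Of 16 alternatives the microglia list kept its call in all 16, heat shock in 15, the cytoskeleton and translation factors in 14, ribosomal proteins in 13, oligodendrocyte markers in 11, the proteasome in 10 and glycolysis in 9. Choroid plexus markers and neuropeptide genes kept theirs in 7 and 6 of 15. The astrocyte list did not pass (adjusted p = 0.704), and its median of -0.24 and mean of 0.07 differ in sign.

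The MECS effect on D4/C2 asks which mRNAs move between synaptosomes and their reference after the seizure. Astrocyte markers had a higher D4/C2 ratio with MECS than without (8 of 11; median difference 0.37, adjusted p = 0.0273 and adjusted p = 0.632 with an estimated correlation). Oligodendrocyte markers had a lower one (10 of 13; median -0.26, adjusted p = 0.0149 and adjusted p = 0.632 with an estimated correlation), as did proteasome genes (14 of 18; median -0.16, adjusted p = 0.0349 and adjusted p = 0.731 with an estimated correlation). Adjusted over the list alone, 2 oligodendrocyte markers fell and 0 members of the other 2 lists passed. The microglia list did not pass (median -0.17, adjusted p = 0.164), with 3 members lower adjusted over the list alone. Limma called 0 of 13109 features, with 1028 at an unadjusted p below 0.05 and a smallest adjusted p of 0.217. That value belonged to amph2, an amphiphysin of membrane recycling (-0.93 ± 0.10, n = 2 against 2). Insulin-like growth factor I (-1.07) and protein kinase C (-0.83) followed on the low side, and phospholipid hydroperoxide glutathione peroxidase (0.80), an alkylated-DNA repair protein (0.73) and V-1 (0.69) on the high side. The astrocyte list lost its call without replicate 1 of the group without MECS and without MECS replicate 2 (adjusted p = 0.245 and 0.501), the oligodendrocyte list without replicate 2 of the group without MECS and without MECS replicate 1 (0.0525 and 0.209), and the proteasome list without those same replicates and without MECS replicate 2 (0.256, 0.283 and 0.0541). The astrocyte median was 0.13 and 0.57 without replicates 1 and 2 of the group without MECS, and 0.64 and 0.09 without MECS replicates 1 and 2. Without these MECS replicates the oligodendrocyte median was -0.15 and -0.40 and that of the proteasome -0.09 and -0.25, and without replicate 2 of the group without MECS that of the proteasome was -0.08. With median centring the astrocyte median was 0.07 (adjusted p = 0.936), and with the spread scaled the oligodendrocyte and proteasome medians were -0.05 and -0.08 (adjusted p = 0.632 and 0.737). Of 18 alternatives the oligodendrocyte list kept its call in 13, astrocyte markers in 9 and the proteasome in 8.

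Genes at both ends of the D4/C2 ratios at baseline had smaller ratios after MECS. The tenth of genes highest in D4 in 1 replicate without MECS, 1282 genes, had a median change of -0.16 and -0.22 when measured against the other replicate, in either order, and 81.6% and 77.5% of them had a lower ratio. With the dyes exchanged, which picks the tenth lowest in D4 under the label dyes, the change was -0.19 and -0.47, and 77.8% and 93.3% of the genes had a smaller ratio. The same measure for HP gave 0.05 and 0.07 over 1200 genes, and -0.03 and 0.0073 with the dyes exchanged. The genes picked as highest in HP had median ratios of only 0.03 and -0.02 in the other replicate without MECS, so they had no enrichment there that could fall. With the dyes exchanged these medians were 0.13 and 0.19. The HP values therefore do not show whether baseline ratios shrank. These changes were computed across replicates so that picking and measuring did not share an array, and they carry no test.

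With 2 features called higher in HP, the genes enriched in HP and in D4 without MECS could hardly be compared. Of 2 features higher in HP and 802 higher in D4, 0 were shared, against 0.123 expected for independent lists. Of 86 lower in HP and 785 lower in D4, 1 was shared, against 5.17 expected (Fisher's exact test, two-sided, p = 0.0642). The log2 ratios of the preparations correlated across genes with r = -0.20 (Spearman's rho -0.16). Without replicate 1 of the HP/LP group, 2 lower features were shared against 20.9 expected (Fisher's exact test p = 2.16e-07), and under the strict filter 3 were shared, fewer than expected (p = 6.02e-05, Fisher's exact test). With MECS, where 0 features were called in HP/LP and 575 had an unadjusted p below 0.05 by limma, the correlation was -0.06, and 0.13 without HP/LP MECS replicate 1 and -0.19 without HP/LP MECS replicate 2. It was -0.02 without D4/C2 MECS replicate 2. The MECS effects of both preparations correlated with r = -0.10, and with r = 0.03 without D4/C2 MECS replicate 1, -0.18 without D4/C2 MECS replicate 2, -0.19 under the strict filter and 0.01 with processed values. That of the MECS effects was -0.06 without replicate 2 of the group without MECS in either preparation.

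The mean signal of both channels compared MECS with non-MECS RNA between arrays. No slide or day of feature extraction held both, so array, slide and day differences are not removed here. Immediate early genes, which neurons switch on within minutes of strong activity, were the list with the higher signal after MECS in both preparations. On the HP/LP arrays, 15 of 21 had a higher signal (median log2 0.41). The set test used the 15 members with a value in all 8 replicates (camera, adjusted p = 5.71e-04 and adjusted p = 0.353 with an estimated correlation). The synaptic pentraxin gene Nptx2 was at 1.46 ± 0.37 (SE, n = 2 against 2), the transcription factor gene Egr4 at 1.27 ± 0.34, Gadd45g at 0.78 and Arc at 0.60. Fos at -0.12, Egr1 at -0.06 and Rheb at -1.08 had 1 MECS replicate each and were not in the set test. On the D4/C2 arrays, 16 of 21 had a higher signal (median 0.28, adjusted p = 4.47e-04 over the same 15 members and adjusted p = 0.353 with an estimated correlation). The Fos-related gene Fra was at 0.90 ± 0.30, Arc at 0.82 ± 0.34, Egr1 at 0.68, Btg2 at 0.50 and Fos at 0.35, with Egr1 and Fos again outside the set test. In either preparation 0 members passed over all features or adjusted over the list alone. Ribosomal proteins on the HP/LP arrays (37 of 54 higher; median 0.07, adjusted p = 0.0422 and adjusted p = 0.751 with an estimated correlation) turned to -0.23 with median scaling of signals and to -0.12 without MECS replicate 1, and had an adjusted p of 0.392 without replicate 1 of the group without MECS. On the D4/C2 arrays, oxidative phosphorylation (22 of 28 lower; median -0.13, adjusted p = 0.00577), the proteasome (15 of 18 lower; median -0.25, adjusted p = 0.00313) and voltage-gated channels (10 of 14 higher; median 0.23, adjusted p = 0.0135) each had an adjusted p of 0.632 with an estimated correlation. Limma called 0 features in both preparations, with 491 and 93 at an unadjusted p below 0.05. The immediate early gene list lost its call on the HP/LP arrays without MECS replicate 1 (adjusted p = 0.120), and on the D4/C2 arrays without replicate 2 of the group without MECS (0.0771) or with MECS (0.143). The other D4/C2 lists lost theirs too: oxidative phosphorylation without replicate 2 of the group without MECS and MECS replicate 1 (0.0947 and 0.446), the proteasome without either replicate 2 (0.194 and 0.101), and the channels without replicate 1 of the group without MECS and MECS replicate 2 (0.415 and 0.501). On the HP/LP arrays the immediate early gene median was 0.12 without MECS replicate 2, and the ribosomal median 0.22 and 0.39 without replicate 2 of the group without MECS or with MECS. HP/LP MECS replicate 2 stood apart in mean signal: it correlated with the other HP/LP replicates at r = 0.82 to 0.89, while those correlated with each other at r = 0.93 to 0.97. On the D4/C2 arrays the immediate early gene median was 0.11 without replicate 1 of the group without MECS, and 0.47 and 0.15 without MECS replicates 1 and 2. There the oxidative phosphorylation median was -0.21 and -0.20 without replicate 2 of the group without MECS or with MECS, and the channel median 0.15 without replicate 1 of the group without MECS and 0.08 without MECS replicate 2. Of 12 alternatives the immediate early genes kept their call in 11 (HP/LP arrays) and 10 (D4/C2 arrays), ribosomal proteins in 6, oxidative phosphorylation and the proteasome in 9 and the channels in 8.

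**Figure D4:**
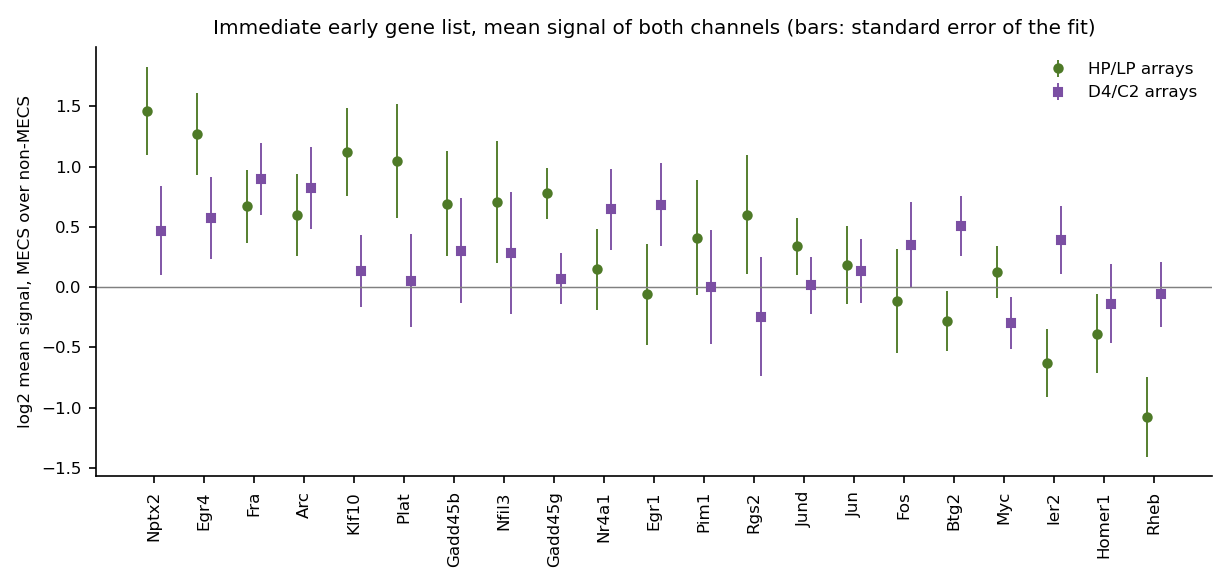
Log2 mean signal of both channels, MECS over non-MECS, for each of the 21 measured immediate early genes on the HP/LP arrays (circles) and the D4/C2 arrays (squares), with the standard error of the fit as bars. The list medians were 0.41 and 0.28, and 0 genes passed singly.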

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

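The tests on the astrocyte list, on the share of ratios kept after MECS and on leaving out 1 HP/LP replicate were chosen only after the result was seen; the last replaced a first test on the gap between replicate medians, once that had been seen, and was then split by list. The test on the share kept in HP/LP replaced one on the ribosomal and proteasome lists, whose ratios without MECS lay too near 0 for it to decide. The lists weighed or named here stood out because the set test found their ratio to differ between rats with and without MECS, or because the data of D4 and C2 differed most.

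Ttr and several microglia markers were among the largest rises in D4 over C2 under the label dyes, and would be among the falls with the dyes exchanged. Without MECS the tables argue against more RNA of every non-neuronal cell type alike, since the astrocyte list had a median log2 D4/C2 of -0.52 (-0.98 to -0.37 over the alternatives) while the microglia list had 1.81 (1.05 to 2.73). With MECS the astrocyte list did not pass (camera, adjusted p = 0.704). Its replicate medians were then -0.33 and 0.05, against 1.88 and 1.35 for microglia. For features lower in D4, an array element that binds RNA other than that of its named gene is a candidate explanation: the other elements of 111 such genes had a median of -0.041, against -1.21. The tested elements were, however, picked for being called and for the highest mean signal of their gene. That choice can leave the others nearer 0, so the comparison does not decide how much such binding contributed. For features higher in D4 that explanation stays open, since the other elements of 115 genes had a median of 0.20 against 0.68, between the values set to decide. The same limit applies there. Under the same choice the other elements kept 29.6% of the tested median for features higher in D4 and 3.36% for those lower. They had the sign of the call in 91 of 115 genes higher in D4 and in 65 of 111 lower. A true difference in what the synaptosome fraction holds, such as microglia or their fragments, and an exchange of D4 and C2 dyes stay open as well and were not tested.

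Ratios of the genes highest and lowest in D4 were smaller after MECS. For the highest, the fall was not confined to features near background. Among features well above background on all arrays the change was -0.28 and -0.21, and the mean fall was 1.29 times that among all features. Those features also had larger ratios without MECS, with medians of 0.83 and 0.79 against 0.44 and 0.54. The comparison therefore cannot tell how much signals near background contributed. The MECS arrays were dimmer in Cy5 only, with medians of 51.1 to 83.7 against 60.3 to 149 without MECS. Their Cy3 medians were 355 to 593, against 272 to 573 without MECS. The D4/C2 ratios of all features had a narrower range with MECS, with an SD of 0.361 and 0.372 against 0.560 and 0.492 without MECS. With the spread scaled between arrays, limma called 828 features without MECS and 728 with MECS. Whether the narrower range came from the measurement or from the RNA stays open. The genes highest and those lowest in D4 kept shares of 0.577 and 0.555 of their ratio. The microglia list kept a share that was larger by 0.35 than that of the tenth of genes lowest in D4, with a spread of 0.35. A redistribution of RNA after the seizure and differences between slides or days were not tested further and stay open.

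Glycolysis and cytoskeleton genes had higher HP/LP ratios after MECS, with list medians of 0.51 and 0.35. A dye effect shared by both orientations of a slide cancels in their mean and so could not give this difference. The median over both lists was 0.37 with HP in Cy3, 0.46 with HP in Cy5 and 0.40 in the mean of both, so neither orientation alone carried it. A dye effect that differs between the 2 arrays of a slide was not tested. The tables argue against 1 replicate as the sole source for the cytoskeleton list, since its lowest median without any 1 HP/LP replicate was 0.34. For the glycolysis list, replicate 2 of the group without MECS is a candidate source, since the median fell to 0.21 without it. The tables lean against a narrower range of ratios on the MECS arrays as the whole cause without settling it. The share of their ratio kept by the genes lowest in HP was larger by 1.04 than that of the glycolysis list (spread 0.54) and by 0.80 than that of the cytoskeleton list (spread 0.50). It ran from 0.36 to 1.51 over pairings of replicates, against -0.41 to 0.05 for glycolysis and 0.06 to 0.19 for the cytoskeleton. These pairings share replicates, so their spread is not one of independent values. A shift of these mRNAs between polysome portions stays open as the biological explanation. Other differences between slides or days stay open too, since no slide or day held arrays both with and without MECS. With median centring the list differences fell to 0.07 and 0.18.

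Other lists differed between ratios with and without MECS by the same set test, and with an estimated correlation 0 of these calls held. The astrocyte list differed by a median of 0.37. The RNA transport list differed by 0.29. The oligodendrocyte list differed by 0.29. The heat shock list differed by 0.26. The neuropeptide list differed by 0.16 and lost its call without each HP/LP replicate in turn. The ribosomal protein list differed by -0.090, and by 0.12 without replicate 1 of the group without MECS. In D4/C2 the astrocyte list differed by 0.37, the oligodendrocyte list by -0.26 and the proteasome list by -0.16.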

How the results depend on the processing

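Array quality weights, leaving out replicate 1 of both HP/LP groups, a crossed pairing of the HP/LP mean signals (0 calls) and exchanged dyes were tests chosen only after the result was seen. The 51 genes named for their largest values kept their direction wherever an alternative gave a value, which leaving out a replicate could not have turned, since they were picked for the same sign in both. Of the 11 in HP/LP, 10 kept their call without replicate 1 and 0 without replicate 2. Of the further genes named as list members or after their values were seen, 10 in HP/LP without MECS kept their direction, with 7 calls left without replicate 1 and 0 without replicate 2. The 56 in D4/C2 without MECS and 30 with MECS kept theirs except Eif5a with D4 in Cy5 (-0.19 and -0.26) and, with MECS and median centring, Hspa8 (-0.0032), Rpl35 (-0.17) and Rpl11 (-0.27). The 88 calls of HP/LP without MECS became 0 with the software's processed values, with scaled spread and with separate fits, 38 with median centring, 35 with the trend and robust variance model, 8 with a replicate block, 4 on the arrays with HP in Cy3, 166 with HP in Cy5, 621 with all 16 arrays in the fit and 1 with array quality weights. Leaving out a replicate gave 2 to 325. HP/LP with MECS, 0 calls, had 1 with median centring, 11 with the strict filter, which tests fewer features, 32 with 16 arrays and 6 with HP in Cy5. D4/C2 without MECS, 1592 calls, had 828 with scaled spread, 2496 with 16 arrays and 694 to 1569 without a replicate. D4/C2 with MECS, 691 calls, had 337 with D4 in Cy3 and 448 to 478 without a replicate. The MECS effects, 0 calls, had 1 (HP/LP) and 4 (D4/C2) with 16 arrays and 1 (D4/C2) with processed values. The mean signal of the HP/LP arrays had 0 to 1 without a replicate. The change of baseline-enriched genes was -0.27 in HP/LP and -0.35 in D4/C2 when picked and measured in the same replicates, which builds in a fall, and -0.29 in D4/C2 with processed values. With exchanged dyes, which picks genes at the opposite end, it was -0.012 in HP/LP and -0.33 in D4/C2. With an estimated correlation 0 list calls remained of 49, and the other alternatives that reran all 160 list tests gave 33 to 51 calls.

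Called list medians that changed sign were these. With median centring: ribosomal -0.13, oxidative phosphorylation -0.060 and proteasome -0.026 (HP/LP with MECS), and ribosomal -0.59 (passed in the opposite direction, adjusted p = 4.12e-09), oligodendrocyte -0.22, glycolysis -0.21, proteasome -0.13 and cytoskeleton -0.030 (D4/C2 with MECS). Heat shock at 0.0054 and astrocyte at 0.058 (MECS effect on HP/LP) kept the sign of their median, while the test's direction turned. By dye orientation: oxidative phosphorylation -0.14 and proteasome -0.0053 (HP/LP without MECS, HP in Cy5), astrocyte 0.057 (HP/LP without MECS, HP in Cy3), RNA transport 0.088 (HP/LP with MECS, HP in Cy3), oxidative phosphorylation -0.044 (HP/LP with MECS, HP in Cy5) and glycolysis -0.013 (D4/C2 with MECS, D4 in Cy5). By other choices: oxidative phosphorylation -0.0057 (HP/LP without MECS, strict filter), ribosomal -0.034 (D4/C2 with MECS, processed values), 0.020 (MECS effect on HP/LP, scaled spread) and -0.23 (mean signal of the HP/LP arrays, median scaling). Leaving out a replicate: proteasome -0.086 to 0.33 (HP/LP without MECS, the lowest without replicate 1 and with replicate 2 alone), translation factors -0.18 to 0.033 (HP/LP without MECS, the highest without replicate 2), ribosomal -0.28 to 0.12 (MECS effect on HP/LP, above 0 without either replicate 1), where replicate 2 alone gave 0.19 and passed in the opposite direction (adjusted p = 0.00532), heat shock -0.071 to 0.39 (MECS effect on HP/LP, the lowest without replicate 2 of the group without MECS), and ribosomal -0.12 to 0.39 (mean signal of the HP/LP arrays, the lowest without MECS replicate 1). The cause was not tested. A slide block was run only in the fit with all 16 arrays, and a day block could not be estimated, since the only shared day lies within 1 group. No slide and no day of feature extraction held arrays both with and without MECS. Differences between slides or days can therefore not be told apart from a MECS effect. Signal over background limits Cy5 on the D4/C2 arrays most, and the strict filter left 3631 of 13184 features.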

Other observations

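Genes with several array elements show how far 1 element stands for its gene. In D4/C2 without MECS, 504 of 1220 such genes had elements on both sides of 0, with a median range of log2 0.19, and with MECS 562 of 1239 did, with a median range of 0.11. In HP/LP, 476 of 1209 genes without MECS and 455 of 1109 with MECS had elements on both sides of 0, with median ranges of 0.13 and 0.082. No test was run on these values.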
